A study of Cyprinus carpio with 16 samples.

How the data were processed

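Head kidney RNA of 16 carp samples was labelled with Cy3 and hybridised to 1 array each, per the labels. The groups K_day0, K_day3, R3_day0 and R3_day3 follow the line and day in the sample titles, with 4 arrays each. The total RNA was isolated with a column kit and amplified with a low-input labelling kit, per the labels' protocols.

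Each array's spot brightness was deposited by the authors as a scanner table with intensity values on a linear scale. The images came from a 1-channel scan and were read with Agilent Feature Extraction 9.5.3.1, per the file headers. The processed signal in these tables is an intensity that was background-subtracted and detrended within the array and not normalized between arrays, per the file headers. The mean and local background intensity of each spot, also deposited, are as scanned. The authors also deposited a table of log2 values for the same arrays. All 16 columns hold the same distribution (median 6.85 in every column), control spots included, and within each array the order is that of mean signal minus background, so these values were read as quantile-normalized net signals. Rows were matched to spots by their order, which that comparison bore out. No label or header states how the table was made, and the submitters' processing notes name limma without a version. The table's log2 base and its direction (higher is brighter) were read from the values, and any offset stays unknown.

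Each array held 11930 spots, of which 536 control spots were left out. The other 11394 belonged to 10974 probes, 42 of them with 11 spots each, which were averaged. Probe names with a contig number were counted as carp and those with positions in the CyHV-3 genome as viral. None of the probes matched the gene table supplied for carp, and the probe descriptions name no gene. The gene lists fixed beforehand search symbols and descriptions, so 24 of the 25 could not be used. The CyHV-3 list was matched through the positions in the probe names in place of descriptions, a departure from the fixed rule.

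The main values were log2 processed signal minus the 75th percentile of the array over unflagged non-control spots, with spots flagged as outliers left out. Probes well above background on every array of at least 1 group were kept, 5830 in all (5821 carp, 9 CyHV-3), of which 4198 were above background on all 16 arrays. Tests used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 16 arrays (12 residual degrees of freedom), eBayes without trend, 5 contrasts and a Benjamini-Hochberg adjusted p threshold of 0.05. The CyHV-3 list was also tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. CyHV-3 measures per array were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9.

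Named probes are, per contrast, at most 2 unnamed contigs with the largest rise and 2 with the largest fall among those past the threshold whose groups do not overlap. Members of the CyHV-3 list are given in full when tested. At least 2 unflagged arrays were required in each compared group, a reading of the rule made after values were seen. Where a probe was not well above background on every array of its dimmer group, the text says so. Where it was on none of the unflagged arrays, a lower bound was taken from these, except for CCC25636_1 and CCC15190_1: the brighter group's mean over, per array, the higher of the lowest signal well above background and the probe's own signal. Bounds and folds of the infection responses are relative to the median shift, but their p-values are not.

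Tested on simulated data with 200 changed probes per contrast among 5426, the method recovered 45 of 100 changes of 1 log2 unit and 88 of 100 changes of 2 log2 units in the K response, with 9 false calls. For the R3 response it recovered 43 and 83 of 100. For the line difference it recovered 46 and 93 on day 0 and 36 and 85 on day 3. For the difference between the responses it recovered 19 and 66. In the real data 2216 of 5518 probes passed in the K response, far more than the simulated changes. The real groups also differed in spread, with a median SD between arrays of 0.28 in R3_day0 and 0.48 in R3_day3. The recovered shares thus hold for the simulated data only and cannot rank the sensitivity of the real contrasts.

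Alternatives chosen before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, the authors' value table, other filters, only the compared groups, trended and robust variances, array weights, stricter thresholds, the replicate number as a block, slide as a block, and leaving out each array in turn. Alternatives added after seeing the data were the percentile over probes detected on all arrays, the percentile over flagged spots too, scaling to 99 spike-in spots above background on every array, centring on the median of the probes tested, keeping flagged spots, requiring 2 unflagged arrays in every group, and the CyHV-3 list without the filter at an estimated correlation. The slide block gives no estimate for the infection responses. Slide follows from the group, so the block leaves the other contrasts unchanged and is no check of them. Brightness limits what can be seen: 3031 carp probes were above background on no array.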

Results

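Transcript levels were measured with custom 1-colour Agilent arrays in the head kidney of common carp (Cyprinus carpio), the organ that serves bony fish as their main site of blood cell formation. Fish of about 120 g from the lines K and R3, kept at 21 °C, were sampled uninfected (day 0) or 3 days after infection with Cyprinid herpesvirus 3 (CyHV-3), a large DNA virus that causes koi herpesvirus disease in carp. Each of the 4 groups (K_day0, K_day3, R3_day0 and R3_day3) had 4 arrays. The submitters call them biological replicates, and the labels do not say whether a sample came from 1 fish or several, so p-values measure the spread between these samples.

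The array held 10974 probes of 60 bases, 10822 of them for carp contigs and 152 for regions of the CyHV-3 genome. Between 5062 and 6589 probes per array were well above background, 46.1% to 60.04% of all probes, and 5830 probes entered the tests. The number of arrays limits the precision of every value. No carp probe was paired with a gene name, so carp probes appear by their contig names, with at most 2 that rose and 2 that fell per comparison. Of the 25 gene lists fixed before the data were examined, only the CyHV-3 list had probes that could be recognised.

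Brightness differed between the groups before scaling. The log2 of the 75th percentile was 8.10 ± 0.27 in K_day0, 7.52 ± 0.35 in K_day3, 8.46 ± 0.27 in R3_day0 and 7.38 ± 0.61 in R3_day3 (SD, n = 4 each). Spots removed as outliers made up 3.50% ± 0.65 and 4.55% ± 0.87 of the spots in K_day0 and R3_day0, against 7.82% ± 1.32 and 7.38% ± 1.55 in K_day3 and R3_day3 (SD, n = 4 each). All day 0 arrays lay on slide 1 and all day 3 arrays on slide 2, so infection and slide cannot be told apart. Within each slide the lines lay in different rows, with K_day0 and R3_day3 in row 1 and R3_day0 and K_day3 in row 2, so line and row cannot be told apart either, and the row changed sides between the days. The first principal component over 3739 probes took 35.5% of the variance and separated K_day3, between 27.9 and 36.9, from K_day0, between -31.0 and -11.9. It also separated R3_day3, between -7.5 and 29.9, from R3_day0, between -22.3 and -17.9, so it follows day, and thus slide, in both lines. R3_day3 replicate 2 stood apart, with a log2 75th percentile of 6.47 and a mean correlation of 0.942 with the other arrays of its group.

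The first question was how the head kidney of line K changed by day 3 of infection. Of 5518 probes with a test, 2216 passed the threshold (limma, adjusted p under 0.05), 1424 of them at least 2-fold. The contig probe CCC03743_1 (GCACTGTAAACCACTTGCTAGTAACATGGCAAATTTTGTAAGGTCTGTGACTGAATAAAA) rose by 5.38 ± 0.37 (SE) log2 units beyond the median probe (limma adjusted p = 2.86e-07). It was not well above background on any K_day0 array, which bounds the rise at 3.58 log2 units or more under the main scaling. Before the median shift is taken off its difference went from 5.72 to 2.27 after normexp and 1.98 in the authors' value table. CCC20245_1 (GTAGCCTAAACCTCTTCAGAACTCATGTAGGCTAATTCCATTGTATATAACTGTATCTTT) rose 39.3-fold on the same scale, by 5.30 ± 0.63 (SE) log2 units (limma adjusted p = 0.000117), with 2 unflagged K_day3 arrays. CCC11371_1 (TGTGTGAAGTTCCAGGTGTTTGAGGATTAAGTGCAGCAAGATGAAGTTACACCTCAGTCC) fell 78.2-fold, with a log2 difference of -6.29 ± 0.93 (SE; limma adjusted p = 0.00111), with 2 unflagged K_day0 arrays. CCC01777_1 (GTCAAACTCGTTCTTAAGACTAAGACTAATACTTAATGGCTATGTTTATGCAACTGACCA) fell, with a log2 difference of -6.22 ± 0.92 (SE; limma adjusted p = 0.00145), and was well above background on 3 of 4 K_day3 arrays. Before the median shift is taken off its difference was -5.89, and it was -5.06 without K_day3 replicate 3, -6.82 without K_day3 replicate 4, -4.55 after normexp and -4.84 in the authors' value table. In the same terms CCC20245_1 went from 5.63 to 4.16 after normexp and 3.801 in the authors' value table.

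The median probe of line K shifted by 0.34 log2 units, and the named differences of both infection responses are relative to the median shift of their line, while their p-values test the differences before that shift is taken off. Of the 2216 probes, 1693 rose and 523 fell, and this split depended on how the arrays were scaled. Rises led with quantile normalization (1542 and 450 falls), after normexp (1699 and 327), with median centring (2084 and 453) and with no filter on dim probes (4192 and 561). The authors' value table gave 1002 rises and 1075 falls. With outlier spots included in the 75th percentile there were 889 rises and 1360 falls, with outlier spots kept throughout 1162 and 1466, with centring on the median of the probes tested 1423 and 737, with the percentile taken over probes detected on every array 643 and 359, and with scaling to the spike-in spots 2669 and 173.

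The same question in line R3 gave 1113 of 5537 probes past the threshold, 590 of them at least 2-fold. CCC05018_1 (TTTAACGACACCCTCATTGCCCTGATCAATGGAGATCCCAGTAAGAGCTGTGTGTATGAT) rose, with a log2 difference of 5.01 ± 1.22 (SE; limma adjusted p = 0.0135). The size rested on single R3_day0 arrays, and the probe was not well above background on replicate 1. Before the median shift is taken off the difference was 5.31. It was 3.57 without R3_day0 replicate 1, 6.47 without R3_day0 replicate 2, 4.08 after normexp and 3.90 in the authors' value table. The call for CCC05018_1 was lost with outlier spots kept (adjusted p = 0.0840) and with the R3 arrays fitted alone (adjusted p = 0.0685). CCC20245_1, named above for line K, rose 18.5-fold in the fit, with a log2 difference of 4.21 ± 0.63 (SE; limma adjusted p = 0.00149). It had 2 unflagged R3_day3 arrays and was well above background on 3 of 4 R3_day0 arrays. Its difference before the median shift is taken off went from 4.51 to 3.54 after normexp and 3.24 in the authors' value table. CCC04206_1 (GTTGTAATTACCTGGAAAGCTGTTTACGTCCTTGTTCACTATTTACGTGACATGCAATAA) fell, with a log2 difference of -4.84 ± 1.08 (SE; limma adjusted p = 0.0103), a call that ended in the authors' value table (adjusted p = 0.0739) and after normexp background correction (adjusted p = 0.0694). CCC03004_1 (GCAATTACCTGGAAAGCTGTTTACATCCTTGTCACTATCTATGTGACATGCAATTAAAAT) fell, with a log2 difference of -4.67 ± 0.77 (SE; limma adjusted p = 0.00285). Without R3_day0 replicate 3 the differences before the median shift went from -4.54 to -3.88 for CCC04206_1 and from -4.37 to -3.83 for CCC03004_1. Without R3_day0 replicate 4 they were -5.45 and -4.96. They were -1.68 and -1.45 after normexp and -2.21 and -1.89 in the authors' value table. The probes of CCC04206_1 and CCC03004_1 share a run of 22 bases, so they are not counted as separate evidence, and neither probe was well above background on any R3_day3 array. Their falls are measured against the floor, with lower bounds of 3.41 and 3.24 log2 units relative to the median shift under the main scaling alone.

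The median probe of line R3 shifted by 0.30 log2 units, with 981 rises and 132 falls. Rises also led with quantile normalization (418 and 87 falls), after normexp (1331 of 1454), with median centring (1948 and 76), with no filter on dim probes (650 and 184) and with centring on the median of the probes tested (853 and 178). The authors' value table gave 471 probes, 240 rises and 231 falls. The counts of rises and falls were 200 and 270 with outlier spots in the percentile, 363 and 336 with outlier spots kept, 43 and 274 with the percentile over probes detected on every array, and 66 and 173 with scaling to the spike-in spots. Quantile normalization gave 505 probes and the R3 arrays alone 663. Without R3_day0 replicate 3 there were 661 probes.

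**Figure D1:**
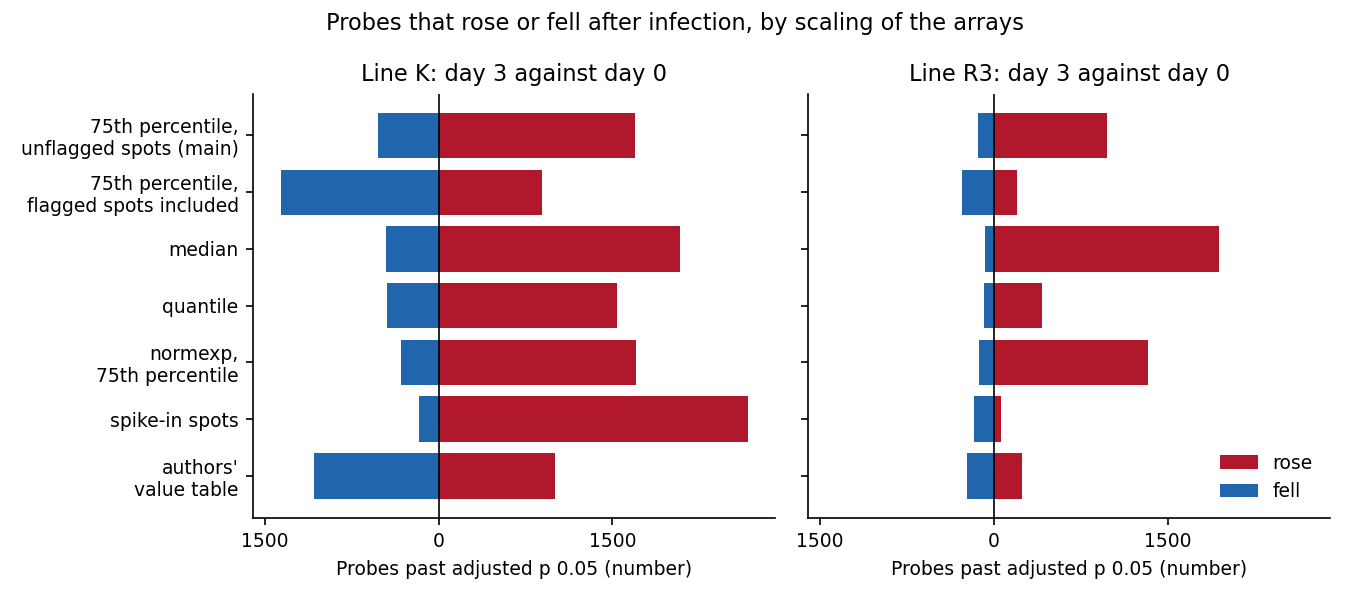
Bars show the number of probes that rose (to the right) or fell (to the left) on day 3 against day 0, past adjusted p 0.05, for line K and line R3 under 7 scalings of the 16 arrays. In line K the split was 1693 rises and 523 falls under the main scaling, and ran from 2669 and 173 with scaling to the spike-in spots to 889 and 1360 when outlier spots entered the percentile.

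The responses of the lines moved together across probes. Over the 5430 probes tested in both lines, 523 rose in both, against 297 if the lists were independent, and 77 fell in both, against 12.6. There were 8 probes past the threshold in opposite directions, each with a fall in K and a rise in R3, and CCC25636_1 alone of them passed the test of the difference. Among them was CCC05018_1, at -4.62 ± 1.16 in K (SE; limma adjusted p = 0.00932) and 5.31 ± 1.22 in R3 before the median shift is taken off, with a difference of 9.93 ± 1.68 (SE; limma adjusted p = 0.0664). Its 2 unflagged K_day3 arrays, at -4.74 and -4.59, were not well above background while the 2 flagged ones were, so the size of its fall in K is not known. The log2 differences correlated across probes with Pearson r = 0.54 and Spearman rho = 0.54, and probes are not independent replicates. No array was shared between the responses, but both compare slide 2 with slide 1, so shared effects of infection and of the slides cannot be told apart. Without R3_day3 replicate 1 the correlation was 0.37, and with dim probes included it was 0.16.

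**Figure D2:**
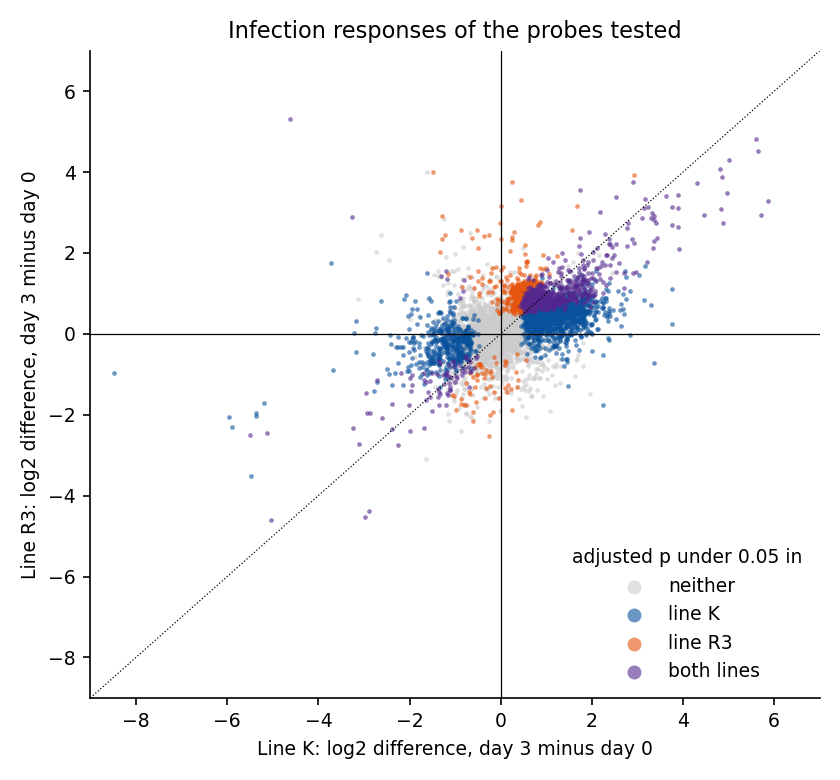
Each point is a probe, with its log2 difference between day 3 and day 0 in line K on the horizontal axis and in line R3 on the vertical axis, coloured by the line or lines in which it passed adjusted p 0.05. Most coloured points lie in the quadrants of equal sign, and 8 probes passed in opposite directions.

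The second question was how the lines differed before infection. Between uninfected R3 and K fish 3 of 5631 probes passed the threshold, and 360 had an unadjusted p under 0.05. CCC06593_1 (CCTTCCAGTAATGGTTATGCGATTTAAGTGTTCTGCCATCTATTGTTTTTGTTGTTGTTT) was 2.94-fold higher in R3_day0 in the fit, with a log2 difference of 1.56 ± 0.23 (SE; limma adjusted p = 0.0269). It was well above background on 3 of 4 K_day0 arrays, and its call held in 6 of the 16 fits that leave out an array. The call was lost after normexp (0.67, adjusted p = 0.215), after quantile normalization (adjusted p = 0.124) and in the authors' value table (0.64, adjusted p = 0.0663). CCC25636_1 (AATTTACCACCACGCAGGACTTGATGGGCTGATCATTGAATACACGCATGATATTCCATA) was lower in R3_day0, at -5.23 ± 0.44 against -3.15 ± 0.32 in K_day0 (log2 level, SD, n = 4 each; limma adjusted p = 0.00985). It was not well above background on any R3_day0 array and lay so near the floor that no fold is given, and its call was lost after normexp (-0.47, adjusted p = 0.654), in the authors' value table (-0.37, adjusted p = 0.193) and with trended, robust variances (0.132). The remaining probe, CCC15190_1 (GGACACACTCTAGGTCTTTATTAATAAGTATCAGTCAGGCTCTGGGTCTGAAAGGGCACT), was chosen after its values were seen. It was lower in R3_day0 (log2 difference -8.40 ± 0.51, SE; limma adjusted p = 0.00461), but this compares 1 unflagged array with 1. The 3 flagged R3_day0 arrays were well above background, and with outlier spots kept its log2 difference was -1.54 (adjusted p = 0.95).

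No probe passed the test between uninfected lines when only probes above background on all 16 arrays were kept, or with outlier spots kept. The numbers that were higher and lower in R3_day0 were 1 and 2 in the main setting, 0 and 2 after quantile normalization or median centring, 0 and 1 after normexp or with the percentile over probes detected on every array, 8 and 2 with scaling to the spike-in spots, and 330 and 10 with no filter on dim probes. The count stays at 3 by design with slide as a block, since both groups lay on slide 1. It was 1 without K_day0 replicate 1, K_day0 replicate 3 or R3_day0 replicate 2, and 5 without R3_day0 replicate 1.

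The third question was how the lines differed 3 days after infection. Of 5464 probes, 291 passed the threshold, 181 higher and 110 lower in R3_day3 than in K_day3. CCC05018_1 was higher in R3_day3, with a log2 difference of 8.62 ± 1.34 (SE; limma adjusted p = 0.0135). Each group had 2 unflagged arrays for it, the 2 flagged K_day3 arrays were well above background where the unflagged were not, and the call was lost with outlier spots kept (log2 difference 5.12, adjusted p = 0.0558) and without R3_day3 replicate 2 (adjusted p = 0.0616). The difference is measured against the floor, with a lower bound of 6.74 log2 units on the unflagged arrays alone, and was 5.07 after normexp and 5.35 in the authors' value table. CCC17275_1 (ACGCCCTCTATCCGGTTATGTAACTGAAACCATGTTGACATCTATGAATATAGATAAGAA) was higher in R3_day3 (log2 difference 5.42 ± 1.17, SE; limma adjusted p = 0.0246) and well above background on 2 of 4 K_day3 arrays. Its call was lost without R3_day3 replicate 2 (adjusted p = 0.0550), R3_day3 replicate 3 (0.0808) or K_day3 replicate 3 (0.0609), and its difference was 3.08 after normexp and 3.21 in the authors' value table. The lines already stood apart in this direction on day 0, with mean log2 levels of 0.43 in R3_day0 and -3.75 in K_day0. That gap did not pass the threshold, but the day 3 difference cannot be put down to infection. CCC00797_1 (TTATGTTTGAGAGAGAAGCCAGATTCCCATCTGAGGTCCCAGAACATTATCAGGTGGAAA) was lower in R3_day3, by at least 7.02-fold under the main scaling (log2 difference -3.61 ± 0.73, SE; limma adjusted p = 0.0202), and CCC03736_1 (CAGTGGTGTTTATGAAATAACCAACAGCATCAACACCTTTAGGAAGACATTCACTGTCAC) at least 4.46-fold lower (log2 difference -3.20 ± 0.60, SE; limma adjusted p = 0.0159). Neither of these was well above background on any R3_day3 array. Both were also lower in R3 on day 0, without passing the threshold there. The mean log2 levels in R3_day0 and K_day0 were -2.22 and -0.87 for CCC00797_1 and -2.98 and -1.60 for CCC03736_1. Only 2 of 4 and 1 of 4 R3_day0 arrays were well above background for them. CCC05018_1 went the other way on day 0, at -1.35 in R3_day0 and -0.04 in K_day0. In the authors' value table neither passed, at -1.01 for CCC00797_1 (adjusted p = 0.0771) and -0.66 for CCC03736_1 (adjusted p = 0.0756), nor after normexp, at -0.89 (adjusted p = 0.153) and -0.57 (adjusted p = 0.260), all below their bounds under the main scaling. Both calls were also lost without R3_day3 replicate 2 (adjusted p = 0.0617 and 0.0518), and that of CCC03736_1 without R3_day3 replicate 3 (adjusted p = 0.0540).

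The number of probes that differed on day 3 rested on single arrays. It was 17 without R3_day3 replicate 2, 29 without R3_day3 replicate 3, 831 without R3_day3 replicate 1, and 89, 72 and 162 without K_day3 replicates 2, 3 and 4 in turn. Fitted on the day 3 arrays alone, 34 probes passed. The count stays at 291 by design with slide as a block, since both groups lay on slide 2. The numbers higher and lower in R3_day3 were 190 and 189 in the authors' value table, 67 and 90 after normexp, 23 and 184 with the percentile over probes detected on every array, 45 and 269 with scaling to the spike-in spots, and 51 and 32 with no filter on dim probes.

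The fourth question was whether infection changed the lines differently. Of 5430 probes, 2 passed the test of the difference between the responses, and 1033 had an unadjusted p under 0.05. For CCC25636_1 the R3 response exceeded the K response by 2.76 ± 0.42 (SE) log2 units (limma adjusted p = 0.0206), with group means of -3.15, -4.35, -5.23 and -3.67 in K_day0, K_day3, R3_day0 and R3_day3. It was well above background on no K_day3 or R3_day0 array and on 1 R3_day3 array, so these values lie near the floor. Its call was lost after normexp (0.43, adjusted p = 0.367) and in the authors' value table (0.30, adjusted p = 0.173). For CCC15190_1, chosen after its values were seen, the difference was 7.52 ± 0.60 (SE; limma adjusted p = 0.0206), and it again rested on 1 unflagged array in K_day0 and 1 in R3_day0. The call for CCC15190_1 was lost with outlier spots kept (4.44, adjusted p = 0.507).

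No probe passed the test of the difference with trended, robust variances or with outlier spots kept. The probes with a larger and a smaller difference in R3 numbered 58 and 54 in the authors' value table, 5 and 4 after normexp, 9 and 3 with outlier spots in the percentile, 2 and 1 with centring on the median of the probes tested, 2 and 4 with the percentile over probes detected on every array, 16 and 1369 with scaling to the spike-in spots, and 162 and 2180 with no filter on dim probes. Leaving out 1 array gave 339 probes without R3_day3 replicate 1, 21 without R3_day3 replicate 4 and 0 without R3_day3 replicate 3. The count was 1, 9 and 1 without K_day0 replicates 1, 2 and 4, was 4, 5 and 4 without R3_day0 replicates 2, 3 and 4, and was 6 and 1 without K_day3 replicates 3 and 4. The count stays at 2 by design with slide as a block, since slide follows from the group, so the block is no check of it.

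The CyHV-3 probes address whether signal at viral sequences changed with infection. Positions are those carried by the probe names, from 1 at the start of the CyHV-3 genome sequence used for the array, and its gene annotation was not used here. Of the 152 regions 9 had a probe bright enough for a test, and these 9 were above background in uninfected fish too. The source of that signal was not tested, so their changes do not measure how much viral RNA was present. In line K 2 of the 9 rose, 1 fell and 6 did not pass, with the same numbers when adjusted over the list alone. As tested, before the median shift is taken off, the region from 45570 to 47375 rose by 1.504 ± 0.50 log2 units (SE; limma adjusted p = 0.0263) and the region from 194842 to 195633 by 0.90 ± 0.31 (SE; limma adjusted p = 0.0312), both on the forward strand. The region from 219317 to 220138 stood at -1.17 ± 0.40 (SE; limma adjusted p = 0.0306) and was well above background on 1 of 4 K_day3 arrays. Relative to the median shift these were 1.17, 0.57 and -1.51. In line R3 the region from 194842 to 195633 alone passed, at 0.95 ± 0.31 (SE; limma adjusted p = 0.0428), or 0.65 relative to the median shift, and 0 of 9 passed when adjusted over the list alone, with 0.0706 as its adjusted p there. The region from 45570 to 47375 stood at 1.05 ± 0.50 in line R3 (SE; limma adjusted p = 0.152), and that from 219317 to 220138 at -0.36 ± 0.40 (SE; limma adjusted p = 0.542), or 0.74 and -0.66 relative to the median shift.

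These calls depended on the setting. In line K the call for 45570 to 47375 was lost with array weights (adjusted p = 0.0545), with outlier spots in the percentile (0.0892), with outlier spots kept (0.0840) and with the percentile over probes detected on every array (0.187), and it held in 14 of the 16 fits that leave out an array. The fall of 219317 to 220138 was lost after normexp (-0.18, adjusted p = 0.468), after quantile normalization (0.0518) and with scaling to the spike-in spots (0.131), and held in 11 of 16. The rise of 194842 to 195633 was lost in both lines with centring on the median of the probes tested (adjusted p = 0.0532 in K and 0.0556 in R3) and in the authors' value table (0.324 and 0.337). It was also lost in both with outlier spots in the percentile (0.282 and 0.177), with outlier spots kept (0.273 and 0.168) and with the percentile over probes detected on every array (0.402 and 0.772). In line K alone it was lost with array weights (0.0631) and with the K arrays alone (0.0701), and in line R3 alone with no filter (0.0877) and with scaling to the spike-in spots (0.463). It held in 10 of 16 such fits in K and 6 in R3. A call was gained as well: the region from 45570 to 47375 passed in line R3 under 1 of 11 alternative settings (limma adjusted p = 0.0385).

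The other 6 regions passed in neither line in the main setting. The region from 202777 to 203493 passed under 1 of 11 alternative settings in K and 2 of 11 in R3. Its result held in 15 of the 16 fits that leave out an array in K and 14 in R3. Relative to the median shift, K and R3 stood at -0.12 and -0.00 for 30877 to 31065, at -0.40 and -0.28 for 62972 to 69325, and at -0.11 and -0.54 for 85871 to 90448, all on the complementary strand. On the forward strand the values were -0.15 and -0.15 for 95866 to 96516 and 0.39 and 0.65 for 202777 to 203493, and on the complementary strand 0.03 and 0.23 for 126122 to 132925. Between the lines 0 of 9 passed, with lowest limma adjusted p-values of 0.920 on day 0, 0.262 on day 3 and 0.437 for the difference between the responses. As a set, the 9 probes did not shift against the other probes in line K (camera p = 0.841) or line R3 (camera p = 0.892), and no set call existed to be lost with an estimated correlation (p = 0.906 and 0.936). The camera p-values for the lines were 0.389 on day 0, 0.363 on day 3 and 0.781 for the difference. In both responses the median and mean log2 difference of these probes were above 0 (0.23 and 0.32 in K, 0.30 and 0.37 in R3). The direction given by fry was up (its p-values were 0.172 in K and 0.184 in R3), while that of camera, relative to the other probes, was down.

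Without the filter on dim probes, 109 of the 152 CyHV-3 regions (71.7%) rose in line K, but so did 68.7% of 3031 carp probes that were above background on no array. In the authors' value table, where each array has the same distribution, 13 of 152 (8.55%) rose in line K and 1 fell, against 1.62% and 1.29% of those dim carp probes. The dim carp probes were chosen for being above background on no array, day 3 included, and the CyHV-3 probes were not. Carp probes that became bright on day 3 were thus left out, so these shares are not drawn alike. In line R3 none of the 152 regions rose and 5 fell in the authors' value table, and none rose and 4 fell without it (limma). Of the dim carp probes 0.69% fell in R3 in the authors' value table and 1.12% without it. K_day3 and R3_day0 lay in slide row 2, so rises in K and falls in R3 cannot be told apart from slide row. Of the 152 probes 31 were well above background on at least 1 uninfected array and 6 on all 8, a signal without infection whose source was not tested.

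**Figure D3:**
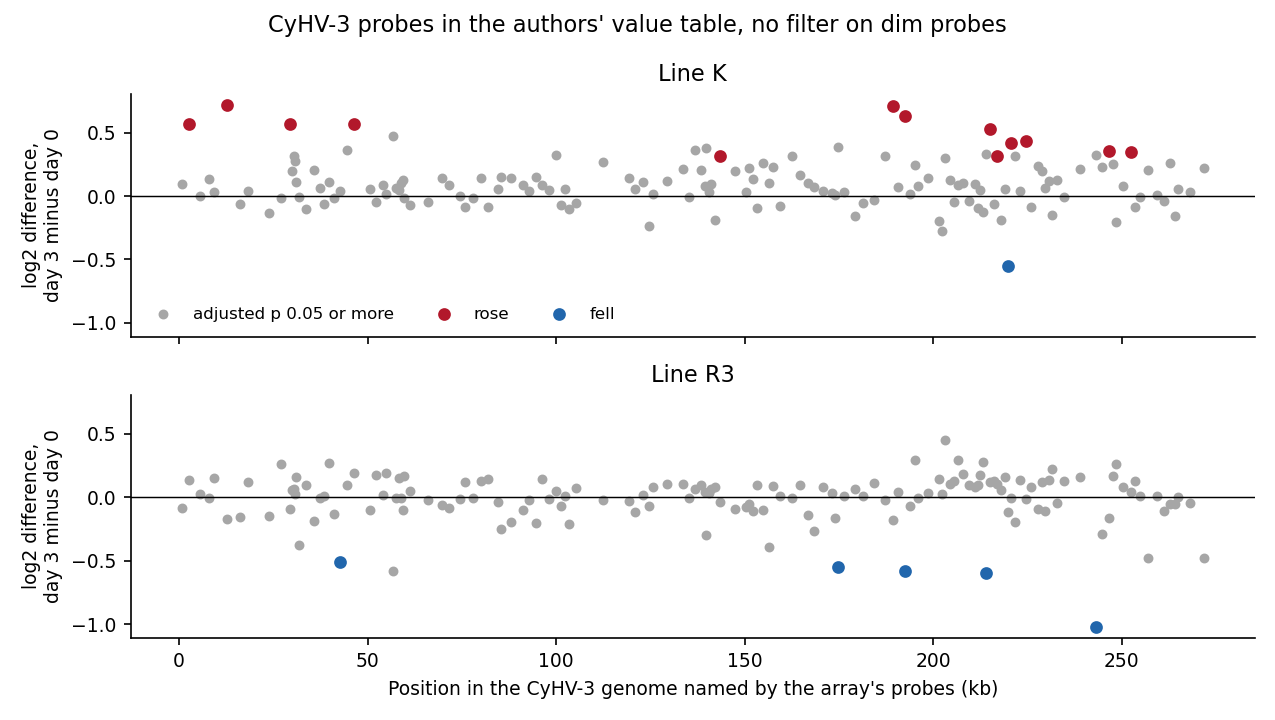
Each point is a CyHV-3 region, placed by its position in the viral genome in kilobases, with the log2 difference between day 3 and day 0 in the authors' value table for line K (upper panel) and line R3 (lower panel). Red points rose and blue points fell past adjusted p 0.05, 13 and 1 in line K and none and 5 in line R3.

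Ranked among the dim carp probes of the same array, the median CyHV-3 probe stood at the percentile 51.1 ± 9.4 in K_day0, 66.5 ± 9.0 in K_day3, 55.6 ± 0.95 in R3_day0 and 56.5 ± 4.8 in R3_day3 (SD, n = 4 each). This measure was chosen after the data were seen and uses net signals (mean minus background). The K response did not pass an exact two-sided permutation test (p = 0.0857, adjusted p = 0.143 over 5 comparisons), nor did the R3 response (exact p = 0.771, adjusted 0.771), the line difference on day 3 (exact p = 0.0571, adjusted 0.143) or the difference between the responses (exact p = 0.0506, adjusted 0.143). With processed signals in place of net signals, the R3 difference was -5.52 (exact permutation, adjusted p = 0.0476) and the difference between the responses -18.7 (adjusted p = 0.00408), so these 2 results depend on the signal used. The smallest p that 4 arrays against 4 allow is 0.0286. The number of CyHV-3 probes above the 95th percentile of dim carp probes was 18.5 ± 4.2 in K_day0, 29.5 ± 10.1 in K_day3, 23.8 ± 3.6 in R3_day0 and 17.5 ± 3.1 in R3_day3 (SD, n = 4 each). Its difference between the responses was -17.25 probes (exact permutation p = 0.00939, adjusted p = 0.0469 over 5 comparisons), while neither response passed by itself (exact p = 0.114 in K and 0.0571 in R3, adjusted 0.143 for both). With processed signals this number passed in the R3 response (-6.75, exact permutation, adjusted p = 0.0476) and between uninfected lines (7, adjusted p = 0.0476). The number of CyHV-3 probes well above background was 13.5 ± 3.3 in K_day0, 12.5 ± 3.7 in K_day3, 13.5 ± 4.1 in R3_day0 and 10.25 ± 1.3 in R3_day3 (SD, n = 4 each). That number did not rise in K (-1, exact permutation p = 0.8). Its difference between the responses was -2.25 (exact permutation p = 0.544, adjusted p = 0.907). P-values were adjusted within each measure, not over the measures. K_day3 lay in row 2 and R3_day3 in row 1, opposite to the day 0 arrays, so the differences between the responses cannot be told apart from slide row.

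**Figure D4:**
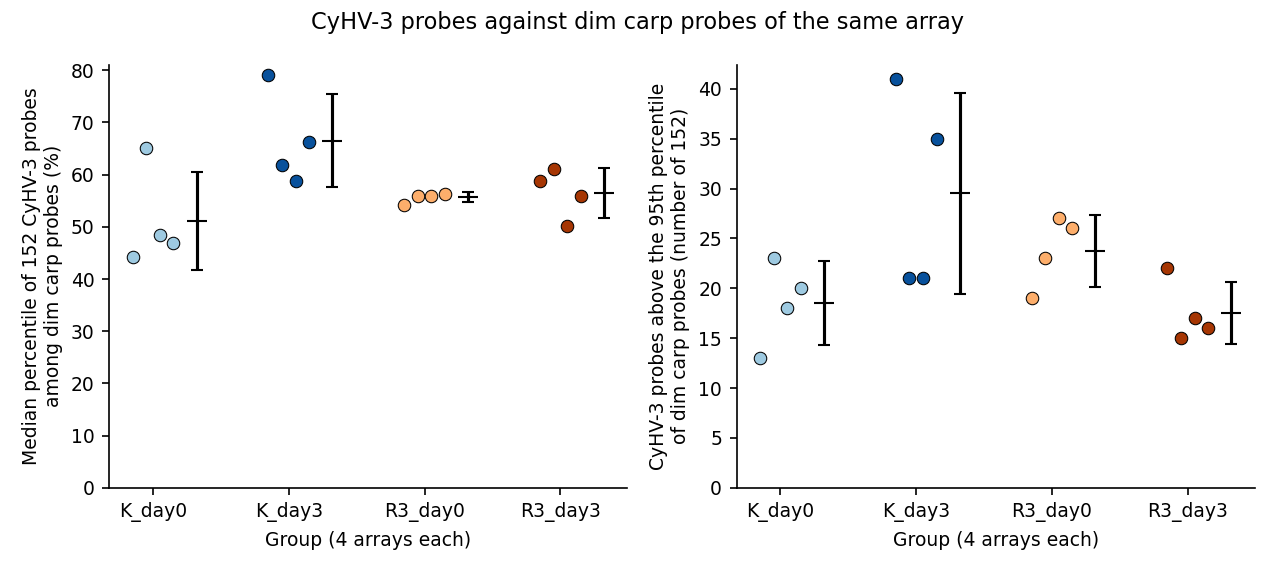
Points are single arrays by group, with the group mean and SD beside them. The left panel shows the median percentile of the 152 CyHV-3 probes among dim carp probes and the right panel the number of CyHV-3 probes above their 95th percentile, where K_day3 arrays span 21 to 41.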

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

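The test that left out R3_day3 replicate 2 was chosen after the counts without single arrays had been seen. The test of spread against size of change was chosen before its result was known.

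Of 104 groups of 4 arrays, 8 had an array far from the others, where chance gives about 1 in 20, or 5.2. R3_day3 replicate 2 had a log2 75th percentile of 6.47, against 7.66 to 7.70 on the other arrays of its group. R3_day0 replicate 4 had 5.85% of its spots removed as outliers, against 4.04% to 4.20%. K_day3 replicate 1 had 18 CyHV-3 probes well above background, against 10 to 11. R3_day0 replicate 1 had the lowest median CyHV-3 percentile of its group, 54.2 against 56.0 to 56.3.

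Single probes had such arrays as well. CCC04206_1 stood at -3.03 (log2 level) on K_day3 replicate 4, above -4.86 to -4.60 on the other K_day3 arrays. CCC00797_1 stood at -1.30 on K_day0 replicate 1, below -0.77 to -0.67. The CyHV-3 region from 45570 to 47375 stood at -1.19 on K_day3 replicate 4, above -2.46 to -2.31, and the region from 126122 to 132925 at -0.77 on K_day0 replicate 1, below -0.31 to -0.21.

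The test of the difference between the responses passed for CCC25636_1, at 2.76 log2 units (R3 response minus K response), and for CCC15190_1, at 7.52 log2 units. The first was near the floor and did not pass in the authors' value table (0.30), and the second rests on 1 unflagged array in each uninfected group. Since 6 of 100 drawn splits gave 2 or more probes, chance is not excluded for this count.

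The K response had 2216 probes past the threshold and the R3 response 1113, but the gap depended on the setting, at 2537 and 2024 with median centring, 2026 and 1454 after normexp, 1992 and 505 with quantile normalization, 2077 and 471 in the authors' value table, 2249 and 470 with flagged spots in the percentile, and 2842 and 239 with spike-in scaling. The tables argue against the array R3_day3 replicate 2 as the reason, since without it the R3 count was 1103 and the K count in the same fit 2638. Scatter was weighed for the 3739 probes with a value on every array, but the comparison cannot decide on it. The median SD between arrays was 0.48 in R3_day3 and 0.38 in K_day3. The error variance subtracted was pooled over the 4 groups, so each of these probes had the same SE in both responses, and each line's own error was not used. The SD of the R3 differences was then 0.739 of that of the K differences (0.693 to 0.788 without single arrays). In the authors' value table it was 0.701 (0.654 to 0.765). With equal SEs, fewer calls go with a smaller spread of differences, so these ratios largely restate the gap in counts. A smaller response in line R3 may remain as a hypothesis, and so may the slide rows, which changed sides between the days and could enlarge one response and reduce the other.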

How the results depend on the processing

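Leaving out single arrays, the number of probes past the threshold ranged from 1755 to 2638 in the K response, 661 to 1202 in the R3 response, 1 to 5 between uninfected lines, 17 to 831 between infected lines and 0 to 339 for the difference between the responses (main values 2216, 1113, 3, 291 and 2). The cause of the changes below was not tested, except where fewer probes, fewer arrays or a stricter threshold make them.

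In the K response the count moved by over 1.5 times with no filter on dim probes (4753), with at least 2-fold (1424), at adjusted p under 0.01 (1311) and with the percentile over probes detected on all arrays (1002). In the R3 response it was 505 after quantile normalization, 2024 with median centring, 471 in the authors' value table, 663 with only the R3 arrays, 590 with at least 2-fold, 363 at adjusted p under 0.01, 317 with the percentile over probes detected on all arrays, 470 with flagged spots in the percentile, 239 with spike-in scaling and 699 with flagged spots kept. Between uninfected lines it was 1 after normexp, 340 with no filter, 0 among probes above background on all 16 arrays, 1 with the percentile over probes detected on all arrays, 10 with spike-in scaling and 0 with flagged spots kept. Between infected lines it was 157 after normexp, 83 with no filter, 34 with only the day 3 arrays, 150 with array weights, 12 at adjusted p under 0.01 and 570 with flagged spots kept. The difference between the responses had 9 after normexp, 23 with median centring, 112 in the authors' value table, 2342 with no filter, 5 among probes above background on all 16 arrays, 0 with trended, robust variances, 56 with array weights, 0 at adjusted p under 0.01, 6 with the percentile over probes detected on all arrays, 12 with flagged spots in the percentile, 1385 with spike-in scaling, 0 with flagged spots kept and 1 with 2 unflagged arrays in every group.

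The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated between -0.34 and 0.27, 3 of 24 pairs were over 0.1, and in 8 of 48 comparisons the closest array had the same number. With the replicate block the counts were 1949, 864, 1, 117 and 0. Among the CyHV-3 regions, the fall of 219317 to 220138 in K and the rise of 194842 to 195633 in R3 lost the threshold with it. With that block camera's direction for the CyHV-3 list turned in the R3 response (camera's p-value 0.974).

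Camera's direction for the CyHV-3 list turned in the K response after normexp (p = 0.499), after quantile normalization (0.861), in the authors' value table (0.406) and with no filter (3.69e-06), and in the R3 response after normexp (0.457), after quantile normalization (0.326), in the authors' value table (0.352) and with only the R3 arrays (0.925). With no filter the R3 response gave 6.13e-07, downward, where the dim carp probes fell as well (median -0.333 against -0.366). Between uninfected lines the list turned after quantile normalization (0.993) and gave 2.00e-12 with no filter, between infected lines it turned with no filter (1.23e-07), and for the difference it turned after normexp (0.963), in the authors' value table (0.919) and with no filter (2.04e-12). These no-filter values rest on the preset correlation: with an estimated one none of the 5 passed (0.353, 0.319, 0.168, 0.291 and 0.168 in the order of the counts), with the directions unchanged from no filter. Without single arrays the camera p ranged from 0.612 to 0.998, 0.204 to 0.995, 0.0107 to 0.660, 0.187 to 0.733 and 0.421 to 0.953 in the order of the counts. The correlation of the responses was 0.16 with no filter and 0.37 to 0.64 without single arrays.

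With processed signals in place of net signals, the median CyHV-3 percentile fell in R3 (-5.52) and passed adjusted p 0.05, as did the difference between uninfected lines (9.502) and between the responses (-18.7). The number of CyHV-3 probes above the 95th percentile then passed in the R3 response (-6.75) and between uninfected lines (7). Without single arrays the R3 percentile difference ran from -0.70 to 3.00.

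Of 1081 values of named probes under alternatives, 937 kept direction and side, 121 lost the threshold, 7 gained it and 16 turned, all of them CyHV-3 regions under the threshold. Region 62972 to 69325 turned in K after normexp (0.24) and with median centring (0.057) and in R3 in the authors' value table (-0.026) and with array weights (-0.32), and without single arrays ran from -0.21 to 0.12 (0.06 without K_day0 replicate 3) in K and -0.28 to 0.19 (-0.03 without R3_day0 replicate 1, -0.05 without replicate 4) in R3. Region 85871 to 90448 turned in R3 after normexp (0.21) and with median centring (0.019). Region 95866 to 96516 turned in R3 with array weights (-0.0064) and ran from -0.021 to 0.41 in K and -0.024 to 0.30 in R3 without single arrays. Region 219317 to 220138 turned in R3 after normexp (0.17) and ran from -0.59 to 0.10.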

Other observations

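The tests of outlier flags, scaling, slide, slide row and viral RNA were chosen after the patterns they weigh had been seen. The counts over other splits of the arrays were planned before.

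In line K, 13 CyHV-3 regions rose past adjusted p 0.05 with no filter on dim probes, both in the scanner values and in the authors' value table, and they were chosen after their values were seen. They were spread along the genome from 1635 to 252909. In the scanner values 109 CyHV-3 regions rose, so that condition removed none of the 13 of the authors' value table and adds no support to them. In the authors' value table the largest rises were 0.72 ± 0.18 (SE) log2 units for the region from 11964 to 13754 (limma adjusted p = 0.0139), on the complementary strand, and 0.71 ± 0.20 (SE) for that from 188007 to 190676 (limma adjusted p = 0.0228), on the forward strand. The smallest p belonged to the forward region from 191317 to 193491, which rose by 0.63 ± 0.12 in K (SE; limma adjusted p = 0.00233) and fell by 0.58 in R3 (limma adjusted p = 0.0135). Its percentile among dim carp probes was 72.3 ± 23.4 in K_day0, 99.8 ± 0.27 in K_day3, 98.3 ± 2.0 in R3_day0 and 58.1 ± 26.1 in R3_day3 (SD, n = 4 each). Of the 13 regions, 6 were well above background on 2 or more K_day3 arrays and 1 on R3_day3 arrays. That region, from 45570 to 47375, was so on all 4 R3_day3 arrays, but also on 3 K_day0 and 2 R3_day0 arrays. The region from 191317 to 193491 was so on 2 R3_day0 arrays, against 2 in K_day3, and that from 11964 to 13754 on 1 R3_day0 array. Over all 152 probes, 8 that were dark on every uninfected array came above background on a K_day3 array (5 without K_day3 replicate 1) and 2 on an R3_day3 array. Since K_day3 and R3_day0 lay in slide row 2, the rises of these regions in K cannot be told apart from slide row.

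CyHV-3 probes lay higher among dim carp probes in K_day3 than in R3_day3, a difference of -10.0 percentile points (R3 minus K). If the second slide row alone raised the CyHV-3 probes, the line differences of day 0 (4.50) and day 3 would cancel. Their sum was -5.53 (exact permutation p = 0.502), which with 4 arrays per group does not show that they cancel. With processed signals the line differences were 9.502 and -9.20. The negative control spots were brighter in row 2 on both slides, by 1.28 log2 units on day 0 and 0.75 on day 3 (exact permutation p = 0.000816 for the row). The percentile is a rank within an array, so a background raised equally for all probes would leave it unchanged. An effect of the second row stays a candidate explanation of the day 3 difference, but how background would cause it was not tested. CyHV-3 RNA in infected line K fish may also account for the day 3 difference: newly bright probes numbered 3.0 ± 2.8 per K_day3 array and 0.50 ± 0.58 per R3_day3 array (SD, n = 4 each), a difference of 2.5 (exact permutation p = 0.171), with 7 of them on K_day3 replicate 1 and a mean of 1.67 on the other K_day3 arrays. With 4 arrays per group and the rows confounded, a part played by viral RNA cannot be told apart from the row.

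More probes rose than fell in both infection responses, 76.4% of the calls in K and 88.1% in R3. Bright spots lost to outlier flags are a candidate explanation, since more spots were removed on day 3: with flagged spots in the percentile the median shift went from 0.30 to -0.023 in R3 and from 0.34 to -0.14 in K. The scaling of the arrays stays open: rises made up 51.0% of the R3 calls and 48.2% of the K calls in the authors' value table, which also differs in signal and flagged spots, but 82.8% and 77.4% with quantile scaling alone and 13.6% and 64.2% with the percentile over probes detected on all arrays. Slide and scan cannot be told apart from infection, and the spike-in spots differed by -0.838 log2 units between the slides (day 3 minus day 0). A change in total RNA per cell was not tested.

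Other splits of the same arrays tested whether chance groupings give as many probes. For the K response 1 of 35 splits, the real one, gave 2216 probes and the highest other split gave 2. For the R3 response 1 of 35 gave 1113 and the highest other gave 2, so no other split came near either count. Each other split mixes day 0 and day 3 arrays in both groups, which adds the day difference to the error. The gap in counts is therefore no measure of chance. Only the rank is, and 1 of 35 is the lowest share possible. Between infected lines 1 of 35 splits gave 291 and the highest other gave 148. The real split ranked first there, but 1 of 35 is the lowest share these splits allow, and 5 contrasts were tested. Chance is therefore not excluded for the count with all arrays. The splits also cannot tell line from slide row, or infection from slide. No splits were run for the lower counts of other fits (17 without R3_day3 replicate 2, 29 without R3_day3 replicate 3 and 34 on day 3 arrays alone). Between uninfected lines 2 of 35 splits gave 3 or more (highest other 3), and for the difference between the responses 6 of 100 drawn splits gave 2 or more (highest other 11), so chance cannot be excluded for either count.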
